A study of Mus musculus with 8 samples.

How the data were processed

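The series held 8 samples of mouse skin keratinocytes, of which 6 were 10x expression libraries and 2 were CellPlex tag libraries of the wild-type sorts. Per the labels' protocols, SmoM2-YFP was induced with tamoxifen in K14CreER mice, skin was digested in trypsin overnight, and CD34-negative YFP-positive cells were sorted from ear and back at 3 weeks and 6 weeks. Wild-type cells came from CD1 mice and were CD34-negative, and the design text adds an alpha6 integrin gate. The labels tie the wild-type expression libraries to their site, and the 6 libraries were grouped by site and condition, 1 per group. The tags were not treated as replicates because the labels do not say what they mark.

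The deposited matrices held UMI counts per gene and barcode, written by Cell Ranger 5.0.0 for the 6-week libraries and 6.1.1 for the others per the file headers. Per the submitters' processing notes, the study used Seurat 4.1.0 and mm10. The feature lists held 31057 genes at 3 weeks, 32286 at 6 weeks with a YFP transcript, and 32285 genes plus 12 tags in wild type, where YFP was not counted. Comparisons used the 30406 genes whose Ensembl ID was in every list.

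Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. Scrublet, as run in scanpy, called doublets per library with its automatic threshold, which removed 6, 6 and 20 cells in back wild type, back 3 weeks and ear wild type. Where it marked under 0.5% of a library of over 5000 cells or found no threshold, the cells with the highest scores at the nominal rate of 0.8% per 1000 cells were removed instead, which gave 162, 191 and 602 cells in back 6 weeks, ear 3 weeks and ear 6 weeks. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 were used without batch integration, since library and condition coincide. A cluster took the name of the type with most markers passing, from 18 lists of markers, with at least 3 markers at 2-fold for epithelial names or 10-fold for other names and present in at least 10% of its cells. The marker lists were written before the data were examined, whereas these naming thresholds were set after the clusters were seen. A cluster whose 10 leading genes held more markers of another type stayed unnamed. Clusters with a median depth under 0.333 of that of their libraries were called low in UMIs, and they stayed unnamed unless at least 2 of their 10 leading genes were markers of the type, as in myeloid cell-like cluster 25, which was not among the keratinocytes.

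Counts of keratinocytes were summed per library and scaled to CPM, the UMIs of a gene relative to all UMIs of those cells. A comparison was the log2 ratio of (CPM + 5), with an exact conditional binomial 95% interval of the count ratio, which covers counting error only. Genes at 20 CPM or more in at least 1 library of a pair were counted when at least 2-fold apart. For 22 gene lists, the median ratio of members at 5 CPM or more was set against 10000 random lists matched on expression in 20 bins, and the percentile is a rank, not a p-value. A fold against a library with 0 counts was taken at a floor of 3 counts. Of 198 list medians, 9 had a member at 0 and moved by at most 0.0738 when it was put at that floor. The difference of ear and back responses had an interval from Poisson draws of the 4 counts. Shares of cells have exact Clopper-Pearson intervals. Cells in cycle were counted after thinning to 1000 UMIs, the largest of 1000, 2000, 3000 and 5000 that at least 80% of cells of each library reached (91.6% for the lowest library). With 1 library per group no p-value was computed.

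Genes named in the text follow a rule fixed before the data were examined: the 10 highest and 10 lowest ratios per comparison, up to 4 members per list with the largest absolute ratio, and Smo, Gli1, Gli2, Ptch1 and Hhip in every comparison; some genes that the rule takes in are not reported here. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor, unnamed and sex-linked genes were left out of the rule. The comparisons, lists, filters and most alternatives were also fixed then. Alternatives covered the cells summed, the scaling, the added CPM, the expression minimum, the filters, the doublets, the weight of cells and the clustering resolution. Others were added after the data were seen: leaving out clusters low in UMIs, only SmoM2 cells with a YFP UMI, leaving out genes whose exons overlap a gene of only some feature lists, centring on genes of like exonic length, and cycling among keratinocytes only.

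The intervals and counts were tested on simulated data made from the libraries with 200 genes changed. The intervals held the true ratio for 95.1% of 6389 genes for ear against back at 6 weeks and 95.3% of 5660 genes for ear at 6 weeks against wild type. Both simulated libraries were Poisson draws from the same profile, as the interval assumes. The simulation therefore checks the code and not the spread between cells or animals. Read alignment, spliced counts and the animals behind the tags were not analysed here. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.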

Results

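The series profiled single keratinocytes of mouse skin after activation of SmoM2, a constitutively active form of Smoothened, the membrane protein that starts Hedgehog signalling inside the cell. SmoM2 was fused to YFP and switched on with tamoxifen in K14CreER mice, where the keratin 14 promoter drives the recombinase and not SmoM2. Cells without surface CD34 but with YFP were sorted from ear and from back skin 3 weeks and 6 weeks later. Wild-type cells of both sites came from CD1 mice, a strain without the transgenes, and were sorted without a YFP gate; the design text adds an alpha6 integrin gate for them. Of 8 samples, 6 were expression libraries, 1 for each combination of site and condition, and 2 were cell tag libraries of the wild-type sorts. No group had a replicate, so every comparison below sets 1 library against 1 other, intervals cover counting error only, and no comparison was tested. An additive model of site and condition over the 6 libraries was not fitted, as any difference between the sites in their response to SmoM2 would enter its residual. Unless another unit is given, the value of a gene is its log2 ratio of (CPM + 5), first group over second, where CPM scales the UMIs of a gene to all UMIs of the keratinocytes of the library. Folds are plain ratios of CPM with their counting interval. Site and Hedgehog state were compared because the series title asks how matrix composition relates to cell competition and to tumour initiation.

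The expression libraries held 4406 barcodes and 19526926 UMIs in back wild type, 4307 and 46732972 in back SmoM2 at 3 weeks, and 8961 and 44696015 in back SmoM2 at 6 weeks. For ear skin the values were 3159 barcodes and 18987541 UMIs in wild type, 9022 and 107746398 in SmoM2 at 3 weeks, and 13112 and 98309019 in SmoM2 at 6 weeks. After the filters on genes and mitochondrial UMIs, 1431, 1438, 4506, 1266, 4882 and 8673 cells were kept in the same order, with medians of 10902, 15077, 4398.5, 9784, 15976 and 7372 UMIs per cell. Removal of doublet calls left 21209 cells. Keratinocytes, meaning all cells outside clusters of other cell types, numbered 1399, 1428, 4086, 786, 4617 and 8002. The wild-type libraries differed from the SmoM2 libraries in strain, sort gate and cell tagging, and the 6-week libraries from the others in Cell Ranger version, so none of these can be told apart from the groups they follow. Itga6, which encodes alpha6 integrin, is in the basal keratinocyte list, so basal and differentiation genes against wild type may follow that gate. Comparisons between SmoM2 libraries do not cross it.

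Clustering gave 34 clusters, of which 9 stayed unnamed and the others took a name from markers. In back wild type, 60.6% of cells (95% Clopper-Pearson interval 58.0 to 63.2) lay in basal keratinocyte-like clusters 5 and 12 and 20.9% in upper hair follicle-like cluster 4. In ear wild type, 33.1% were basal keratinocyte-like and 30.2% T cell-like (27.6 to 32.8), the latter in a sort that was CD34-negative without a YFP gate. In the YFP-sorted libraries, T cell-like cells made up 0.209%, 0.322%, 0.746% and 0.248% of back 3 weeks, back 6 weeks, ear 3 weeks and ear 6 weeks. Back SmoM2 at 3 weeks held 38.4% upper hair follicle-like cells and 11.5% sebaceous gland-like cells, back SmoM2 at 6 weeks 43.0% differentiated keratinocyte-like cells, ear SmoM2 at 3 weeks 26.7% cycling-like cells, and ear SmoM2 at 6 weeks 36.4% lower hair follicle-like cells. Stress genes led some named clusters: Ccl2 and Slpi in upper hair follicle-like cluster 3, Krt6b and Sprr1b in differentiated-like cluster 15, and Fos was among the leading genes of differentiated-like cluster 1. With 1 library per group, a cluster mostly of 1 library may be that library, not a type, and 10 clusters drew at least 90% of their cells from 1 library. Genes that define the clusters differed between the groups, so class sizes are given per library and not compared. Some shares depended on the clustering. At a Leiden resolution of 0.5, basal keratinocyte-like cells made up 3.13% of ear wild type, where 36.2% were unnamed, and sebaceous gland-like cells 24.8% of back SmoM2 at 3 weeks. That sebaceous share was 5.17% with at least 1000 genes and at most 5% mitochondrial UMIs per cell. At a resolution of 2, upper hair follicle-like cells made up 5.33% of back wild type and 16.5% of back SmoM2 at 3 weeks, and unnamed clusters 16.1%, 44.5% and 35.5% of back wild type, back SmoM2 at 3 weeks and ear SmoM2 at 6 weeks. Unnamed clusters held 0.561%, 22.6% and 35.1% of cells in back wild type, 3 weeks and 6 weeks, and 5.86%, 40.8% and 14.4% in ear. Clusters of low UMI counts among them held 16.0% of back and 11.7% of ear cells at 6 weeks, and at most 1.96% in the other libraries.

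The transgene was read first. The YFP transcript, counted in the SmoM2 libraries alone, stood at 37.0 CPM over keratinocytes in ear at 3 weeks (95% interval 35.7 to 38.3) and 9.20 CPM in back at 3 weeks (8.10 to 10.4). At 6 weeks the values were 39.9 CPM in ear and 35.4 CPM in back. A YFP UMI was seen in 41.4% of ear and 12.7% of back keratinocytes at 3 weeks, and in 27.9% and 20.2% at 6 weeks. Among cells of other types, which should lack the transgene, the shares were 16.2% in ear at 3 weeks, 8.70% in ear at 6 weeks and 3.10% in back at 6 weeks, and only 4 such cells were found in back at 3 weeks. T cell-like cells of ear at 3 weeks also held Krt17 at 6821 CPM, so some of these cells may be mixed with keratinocytes or their RNA. Median depths were 15789, 15010.5, 7350.5 and 4658.5 UMIs for the keratinocytes of ear and back at 3 and then 6 weeks, against 8278.5, 7998, 4943 and 1842 for the other cells. Smo itself, whose reads the labels do not separate from those of the transgene, was higher with SmoM2 in all 4 comparisons, with log2 ratios of 1.06, 0.51, 0.50 and 0.70 for ear at 3 and 6 weeks and back at 3 and 6 weeks; in basal-like clusters of ear at 3 weeks it stood at -0.18.

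In back at 3 weeks, YFP and the Hedgehog receptor gene Ptch1 were both low in most cells. Clusters 4, 5, 18, 19 and 22, with 1076 cells or 75.4% of keratinocytes, held 3.74 CPM of YFP and 28.0 CPM of Ptch1, while clusters 1 and 14, with 170 cells, held 35.6 and 481 CPM. The high Ptch1 lay in cluster 14 (104 cells), with 27.0 CPM of YFP and 676 CPM of Ptch1. Differentiated-like cluster 1 (66 cells) held 54.4 and 55.8 CPM. In ear at 3 weeks, clusters 4, 12, 18 and 24 held 14.3% of keratinocytes with 6.26 CPM of YFP and 55.6 CPM of Ptch1, and 8 other clusters held 80.7% with 42.0 and 911 CPM. Among clusters that carried YFP, Ptch1 followed the class: in back at 6 weeks it ranged from 28.8 CPM in differentiated-like cluster 23 and 34.1 CPM in basal-like cluster 5 to 1297 CPM in lower hair follicle-like cluster 26, with YFP at 24.0, 27.4 and 35.2 CPM. In ear at 6 weeks it ran from 88.7 CPM in differentiated-like cluster 15 to 998 CPM in lower hair follicle-like cluster 0, with YFP at 53.3 and 35.2 CPM.

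**Figure D1:**
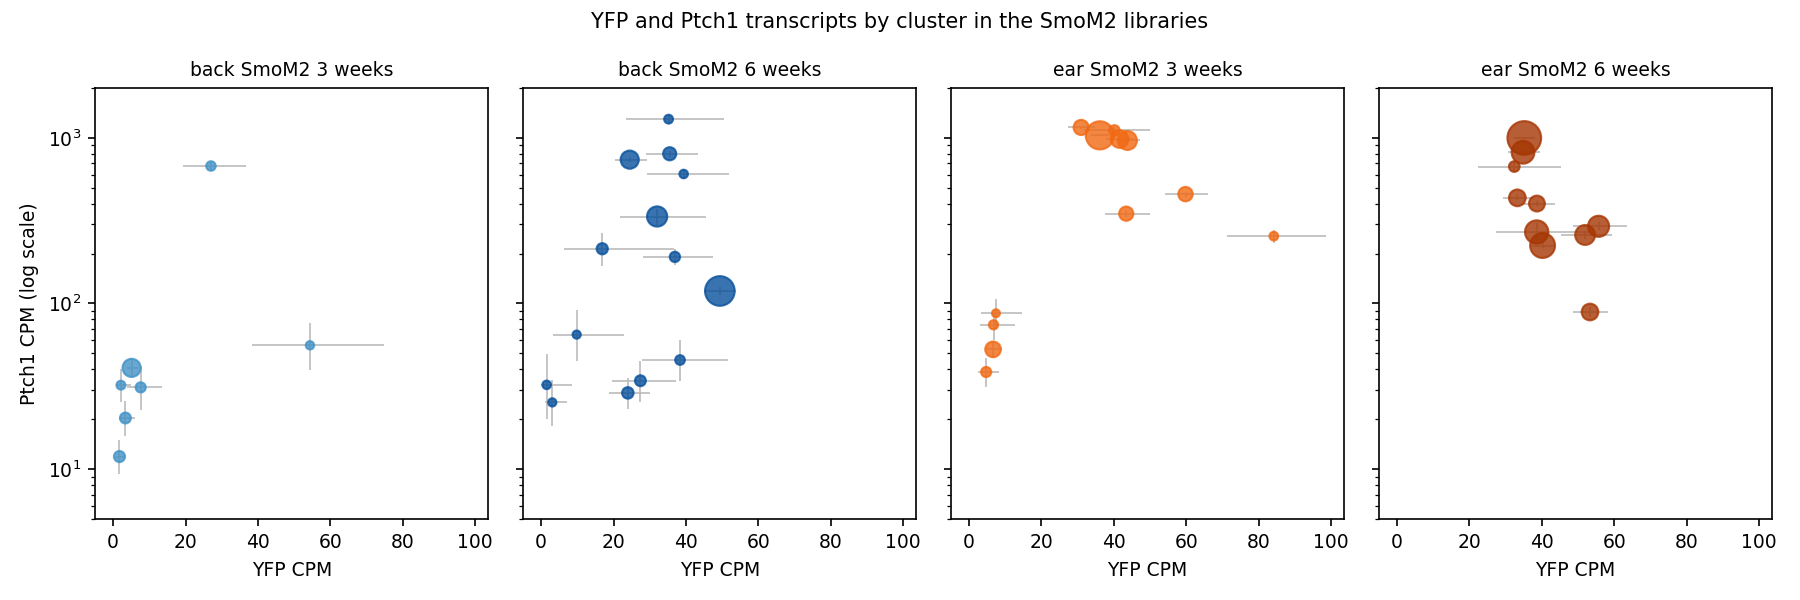
YFP transcript (x axis, CPM) against Ptch1 transcript (y axis, CPM, log scale) for each cluster of at least 50 cells in the 4 SmoM2 libraries, where points are clusters sized by their cells and bars are 95% Poisson intervals. In back at 3 weeks 5 clusters lie near the origin with 3.74 CPM of YFP together, while the clusters of ear at 6 weeks lie between 32.4 and 55.7 CPM of YFP.

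Ear skin 3 weeks after induction was compared with ear wild type to see what SmoM2 did early at this site. Hedgehog targets and wound keratins were higher in the SmoM2 library. Ptch1, which encodes the Hedgehog receptor and is itself a target, stood at 781 against 18.2 CPM (43.0-fold, 95% interval 37.5 to 49.5), and Gli1, the transcription factor that reports pathway activity, at 78.4 against 0.962 CPM (81.5-fold, 95% interval 45.5 to 163). Krt17, a keratin of hair follicles and of injured epidermis, was the highest transcript of this set at 10398 against 189.8 CPM (54.8-fold, 95% interval 52.5 to 57.2). The Hedgehog list had a median log2 ratio of 1.74 with 12 of 17 measured members at least 2-fold higher and 0 lower, the 100th percentile among random lists, and Gli2 and Mycn stood at 2.88 and 3.20. The median over all genes lay at 0.19, so these ratios exceed it by far.

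Wound and stress genes had a median of 2.31, with 9 of 11 higher: Krt6a, a keratin induced by wounding, stood at 370.3 against 9.53 CPM, log2 ratio 4.69, S100a8 at 103 against 0.3497 CPM, log2 ratio 4.34, and its partner S100a9 at 236 against 0 CPM (at least 899-fold higher). Of the embryonic hair follicle and placode genes, 9 of 21 were higher (median 0.89), among them Lhx2, a stem cell transcription factor (2.89), and Sostdc1, a Wnt and BMP antagonist (1.94). Matrix genes split, with 10 of 29 higher and 3 lower. Tnc, a glycoprotein of remodelled matrix, stood at 231 against 6.99 CPM, Col4a1 and Col4a2, which encode chains of basement membrane collagen, at 3.22 and 2.59 on the log2 scale, and Hspg2, which encodes perlecan, at 3.14. Pi15 (322 against 0.175 CPM; 1843-fold, 95% interval 510.2 to 15221), Creb5 (5.23), Dio2 (4.05) and Dcn (4.19) were also among the 10 highest. Of the Wnt list 7 of 25 were higher (median 0.44), with Wnt6 at 2.08 and Wnt7b at 2.04.

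Of 16 basal keratinocyte genes 3 were at least 2-fold lower and 1 higher, and of 15 interferon and antigen genes 3 were lower and 0 higher. Krt15, a basal and stem cell keratin, stood at 897 against 7501 CPM, log2 ratio -3.06, the metallothioneins Mt2 and Mt4 at -1.66 and -2.75, and the class I antigen gene H2-K1 at -1.57. G2/M genes had a median of 0.95 (23 of 52 higher, 0 lower) and S phase genes one of 0.60 (3 of 43 higher, 1 lower), with Top2a at 1.71. Integrin and differentiation lists lay near 0 (medians -0.04 and -0.03). In all, 357 genes were at least 2-fold higher and 190 lower of 6498 at 20 CPM, a split that became 261 and 254 with median-of-ratios size factors. Among basal-like clusters alone, where YFP stood at 6.77 CPM, the Hedgehog median was 0.14 (with no minimum expression 1.06 over all keratinocytes) and Wnt7b stood at -0.0876.

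Of the 10 lowest genes, 9 belong to a set low in both 3-week libraries, such as Nme2 (14.2 against 757 CPM), Atp6v0c (0.867 against 162 CPM), Rnasek, Timm23 and Tomm6. Of 52 genes at least 2-fold lower in both 3-week libraries than in each of the others, 34 (65.4%, 50.9 to 78.0) shared exons with gene models that only the 3-week feature lists hold, against 2.17% of all 11109 expressed genes.

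At 6 weeks wound, barrier, follicle and Hedgehog genes were higher in ear than in ear wild type. S100a9 stood at 660.2 against 0 CPM (at least 2518-fold higher), Krt6a at 1851 against 9.53 CPM (194-fold, 95% interval 161 to 237) and Sprr1b, a cornified envelope precursor of stressed epidermis, at 474 against 0.262 CPM (1807-fold, 95% interval 618 to 8763). The whole wound list was higher, 15 of 15, with a median of 4.61, or 4.53 with genes at 0 in wild type set to the floor of 3 counts. Dissociation and immediate early genes were also higher, 8 of 24 with 0 lower (median 0.72). Differentiation genes of interfollicular epidermis followed, 15 of 21 higher and 2 lower (median 1.54): Flg, which encodes filaggrin, stood at 175 against 0.0874 CPM (1997-fold, 95% interval 358 to 78881), and Lor, which encodes loricrin, at 104 against 5.59 CPM, log2 ratio 3.37. Klk7, a protease of corneocyte shedding, had a log2 ratio of 5.13, and Asprv1, a filaggrin protease, one of 5.52. Differentiated-like cells numbered 47 of 1246 in ear wild type and 1138 of 8071 in this library. The alpha6 gate of wild type was not separated from SmoM2 here.

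Hedgehog genes stayed above wild type at a median of 1.75 (12 of 18 higher, 2 lower), with Ptch1 at 486 against 18.2 CPM, log2 ratio 4.41, Gli1 at 3.39 and Hhip, a ligand-binding antagonist of the pathway, at 3.10. Embryonic hair follicle genes had a median of 1.88 with 15 of 22 higher and 0 lower: Lhx2 stood at 269.6 against 13.99 CPM, log2 ratio 3.85, the stem cell receptor gene Lgr5 at 102 against 6.29 CPM, log2 ratio 3.24, and Ncam1 at 48.2 against 0.175 CPM (276-fold, 95% interval 76.3 to 2278). Wif1, a secreted Wnt inhibitor, and Lef1, a Wnt effector, stood at 3.45 and 1.86. Upper hair follicle genes such as Klk10 (3.52) were higher for 9 of 13 measured members.

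Matrix genes again split, 11 higher and 5 lower of 30, with Vcan, which encodes versican, at 2.69, Fbln1 at 2.54 and Tnc at 2.58. The epithelial integrin gene Itgb6 stood at 2.36, the hyaluronan receptor gene Cd44 at 1.82, and the proteases Mmp13 (27.8 against 0.0874 CPM; 318-fold, 95% interval 57.0 to 12554) and Adamts1 (1.76) were higher, while Mmp3 was lower (-1.52). Of 16 basal genes 6 were lower and 0 higher (median -0.71), with Krt15 at 1416 against 7501 CPM, log2 ratio -2.40 and Thbs1 at -2.04. Krt2, a keratin of ear and tail interfollicular epidermis, stood at 51.7 against 908 CPM, log2 ratio -4.01, and Fcgbp and Serpinb7 at -4.87 and -4.16. The counts were 513 genes higher and 236 lower of 6544, or 426 and 304 with median-of-ratios size factors, around a median of 0.18.

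The same comparison in back skin asked how a second site responded to SmoM2. At 3 weeks lipid synthesis genes of sebaceous glands stood out: 16 of 16 measured members were higher, with a median of 3.50. Scd1, which desaturates fatty acids, stood at 2179.6 against 34.4 CPM (63.3-fold, 95% interval 58.1 to 69.1), the elongase gene Elovl6 at 1557 against 18.6 CPM, log2 ratio 6.05, the lipid droplet gene Cidea at 5.79 and the ceramide synthase gene Cers4 at 6.28. Fa2h stood at 378 against 0.129 CPM (2918-fold, 95% interval 808 to 24099), and the cholesterol gene Idi1 at 4.79. Within sebaceous gland-like cluster 19, Scd1 stood at 8841 CPM in this library and 7558 CPM in ear SmoM2 at 3 weeks. In this library the cluster held YFP at 1.74 CPM and Ptch1 at 11.9 CPM, beside 12.7 CPM of Ptch1 over keratinocytes of back wild type. In the other classes of this library Scd1 stood at 51.9 to 370 CPM, so its sum over keratinocytes rests mostly on this cluster. The cluster held 164 cells of this library and 1 of back wild type, too few for a wild-type level within it. The Scd1 ratio therefore mostly follows how many such cells were caught, and a change of level within them cannot be told.

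Hedgehog genes had a median of 0.87 with 7 of 16 higher and 0 lower, in a library where 75.4% of keratinocytes lay in clusters of low YFP. Ptch1 stood at 126 against 12.7 CPM (9.89-fold, 95% interval 8.56 to 11.5) and Gli1 at 14.04 against 0.129 CPM (108-fold, 95% interval 29.8 to 899). Among cells with a YFP UMI the median was 1.60, in basal-like clusters 0.39 and with median-of-ratios size factors 0.57. Embryonic hair follicle genes were higher for 11 of 19 (median 1.02), with the adhesion gene Alcam at 2.53, Lhx2 at 2.44, the stem cell factor Sox9 at 2.33 and Krt17 at 2038 against 571 CPM, log2 ratio 1.83. Upper hair follicle genes were higher for 11 of 13 (median 1.30), with Krt79 at 1.93 and Fst, which encodes the activin antagonist follistatin, at 1.67. Tnc stood at 54.0 against 1.10 CPM, log2 ratio 3.27, Itgb8 at 2.09 and the TGF-beta gene Tgfb3 at 2.11.

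Basal keratins were lower, with Krt15 at 4414 against 12335 CPM, log2 ratio -1.48, Krt5 at -1.15 and Krt14 at -1.05. Among basal-like clusters alone, which were named by markers of this kind, the basal list turned from -0.66 to 0.42, with Krt5, Krt14, Sparc and Smoc2 at 0.24, 0.14, 0.45 and 0.14. The desmosomal cadherin gene Dsg3 stood at -1.91, Sparc at -1.96 and Smoc2 at -1.59, and the scavenger receptor gene Colec12 at 0 against 53.5 CPM (at least 484-fold lower). Colec12 was thus undetected also in the clusters of low YFP, which held 75.4% of keratinocytes. Its ratio is therefore not read as a response of cells with the transgene, and strain was not separated from SmoM2. The other 9 of the 10 lowest genes, headed by Nme2, were those low in both 3-week libraries. Matrix and protease lists had medians of 0.14 and 0.27, both of which turned negative with size factors (-0.12 and -0.01). Counts were 542 higher and 176 lower of 6414, or 376 and 318 with median-of-ratios size factors, around a median of 0.24.

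By 6 weeks Hedgehog targets and barrier genes were higher in back skin. Ptch1 stood at 334 against 12.7 CPM (26.4-fold, 95% interval 22.9 to 30.5), Gli1 at 48.9 against 0.129 CPM (378-fold, 95% interval 104 to 3122) and Gli2 at 48.1 against 0.777 CPM, log2 ratio 3.20, and the Hedgehog list had 9 of 16 members higher and 0 lower (median 1.38, or 0.21 in basal-like clusters and 0.70 with no minimum expression). Tnc was the highest gene of all at 202 against 1.10 CPM (184-fold, 95% interval 115 to 315), with Pi15 at 5.03, Dcn at 4.60 and Nptx1 at 4.42. Krt17 stood at 6411 against 571 CPM, log2 ratio 3.48, Lgr5 at 3.42, Alcam at 3.26 and Lhx2 at 2.90, and 10 of 20 embryonic follicle genes were higher.

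Differentiation genes were higher for 17 of 21 (median 1.64), with Flg2 at 45.5 against 0.324 CPM, log2 ratio 3.25, Lor at 2.67 and Krtdap at 4009 against 841 CPM, log2 ratio 2.25, and of the cell junction genes 9 of 21 were higher (median 0.85), Dsg1a at 1.66 and Gjb6 at 2.33. Differentiated-like cells numbered 187 of 1425 in back wild type and 1870 of 4344 in this library, and the alpha6 gate was again not separated from SmoM2. Wound genes had a median of 2.24 (7 of 8 higher): Krt6a stood at 109 against 7.64 CPM and Krt16 at 79.3 against 4.98 CPM. Sebaceous genes were still above wild type (13 of 14, median 2.35), with Elovl6 at 4.00 and Fabp5 at 3.82. Sebaceous gland-like cluster 19 (63 cells here, 1 in back wild type) held YFP at 3.08 CPM, Ptch1 at 25.2 CPM and Scd1 at 6582 CPM. In differentiated-like cells Scd1 stood at 233 CPM, against 41.6 CPM in those of back wild type. The sebaceous sums thus mix cells low in YFP with others and are not read as responses of cells with the transgene. The receptors Cd44 and Itgb5 stood at 2.35 and 2.15, Vcan at 37.0 against 0.0647 CPM (572-fold, 95% interval 102 to 22617), and Notch3 at 2.04.

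Lower transcripts included Krt15 (2065 against 12335 CPM, log2 ratio -2.58), Krt14 (-1.87), the matrix genes Thbs2 (-2.60) and Sparc (-2.30), the interleukin-1 decoy receptor gene Il1r2 (-2.75), Colec12 (-3.46) and Fcgbp (-2.40). In basal-like clusters Il1r2 and Fcgbp stood at 0.0131 and 0.23. Colec12 was already undetected in back at 3 weeks, also in clusters of low YFP. Its ratio is not read as a response of cells with the transgene here either. The count of 636 higher and 131 lower genes of 6619 became 321 and 372 with median-of-ratios size factors, and the median of all genes moved from 0.32 to -0.10; the matrix, integrin and G2/M medians (0.14, 0.33 and 0.25) turned to -0.15, -0.06 and -0.09. Long transcripts were higher than short ones in this comparison, with medians of 0.57 in the longest and -0.15 in the shortest of 5 length bins.

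**Figure D2:**
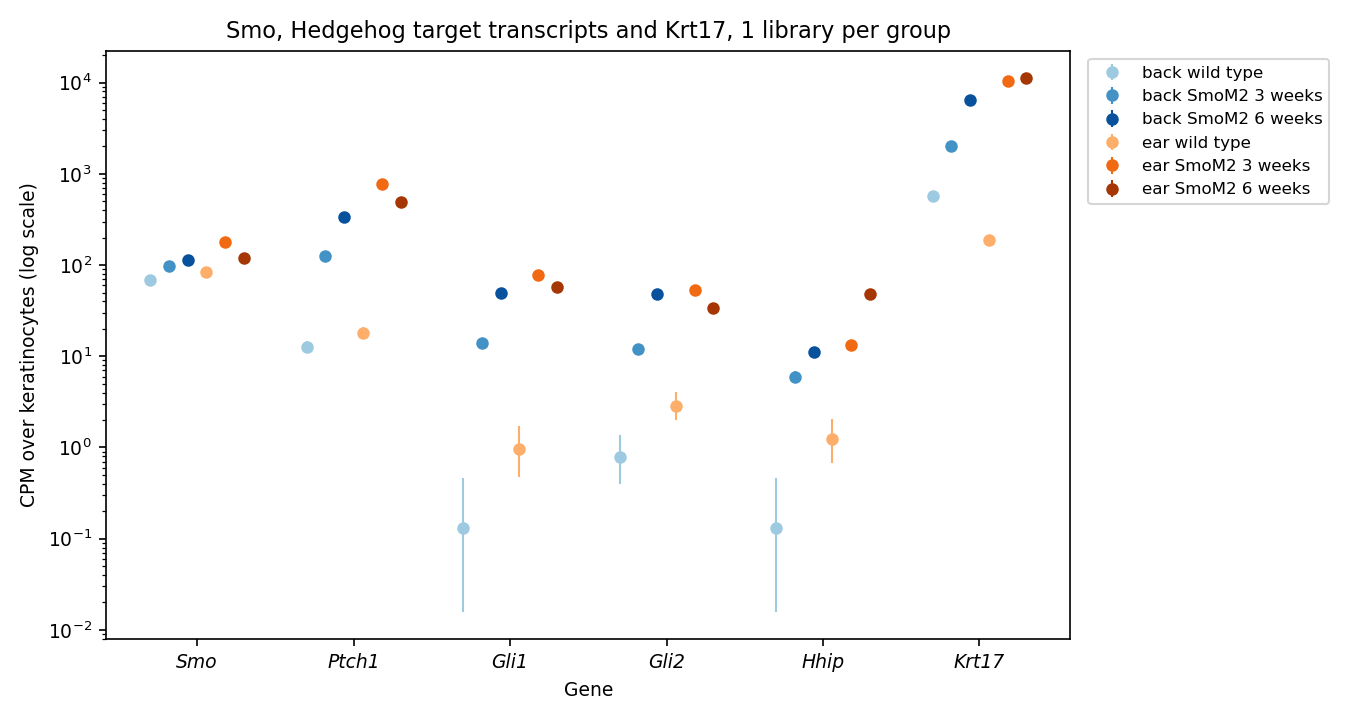
Level over keratinocytes (y axis, CPM, log scale) of Smo, 4 Hedgehog target genes and Krt17 (x axis) in the 6 libraries, where points are libraries and bars are 95% Poisson intervals for counting error. Ptch1 lies at 12.7 and 18.2 CPM in the wild-type libraries and between 126 and 781 CPM in the SmoM2 libraries.

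Wild-type ear and back were compared to see how the sites differed before any activation. Krt2 stood at 908 against 9.06 CPM (100.2-fold, 95% interval 84.8 to 119) in ear against back, and Krt77, a suprabasal keratin, at 8.65 against 217 CPM (25.0-fold lower, 95% interval 20.5 to 30.9). The positional genes Hoxa7 (-3.95), Hoxc8 (-2.83) and Hoxa5 (-2.53) were lower in ear, Hoxb7 stood at 0.0874 against 23.2 CPM (266-fold lower, 95% interval 47.4 to 10530.2), and the homeobox gene Tlx1 was higher in ear (3.46). Sebaceous genes were higher in ear (11 of 14, median 1.94), with Mgst1 at 465 against 30.9 CPM, log2 ratio 3.71.

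Igfbp2, an insulin-like growth factor binding protein gene, stood at 4.68, the matrix protease gene Mmp3 at 37.9 against 1.49 CPM, log2 ratio 2.72, Thbs1 at 2.15 and Ccn2, a target of YAP, at 2.15. G2/M genes had a median of 0.85 (18 of 51 higher in ear) with Mki67 at 1.64. The Hedgehog list lay at 0.28 with 1 member higher and 1 lower of 11, and Ptch1 at 18.2 against 12.7 CPM, log2 ratio 0.39. The matrix, integrin and basal lists lay at 0.14, -0.04 and -0.11. Of 17 interferon and antigen genes 8 were lower in ear and 0 higher, with B2m at -1.66 and H2-K1 at -1.55. The counts were 179 higher and 91 lower of 5944 genes, or 147 and 138 with median-of-ratios size factors.

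After 3 weeks of SmoM2 the sites were set side by side. Wound genes were higher in ear and sebaceous genes higher in back. S100a9 stood at 236 against 6.15 CPM (38.3-fold, 95% interval 32.9 to 44.9), Krt6a at 370.3 against 13.7 CPM (27.0-fold, 95% interval 24.4 to 30.0) and Krt16 at 3.65, with 9 of 10 wound genes higher and 1 lower (median 2.36). Ptch1 was 6.22-fold, 95% interval 6.01 to 6.44, higher in ear, Gli1 stood at 2.13 and Mycn, a proto-oncogene induced by Hedgehog signalling, at 2.53 (list median 0.80, 8 of 18 higher; 0.42 among cells with a YFP UMI and 0.0900 in basal-like clusters). In cells with a YFP UMI the Ptch1 ratio was 2.10 (1.99 to 2.20, 1912 ear and 182 back cells) and the Hhip ratio 0.528 (0.432 to 0.650), against 2.21 (1.87 to 2.63) over all keratinocytes, beside a 4.02-fold ratio of YFP itself (3.53 to 4.59).

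Of 29 basement membrane and matrix genes 9 were higher in ear and 2 lower (median 0.60), with Col4a1 at 203 against 33.9 CPM, log2 ratio 2.42, Hspg2 at 2.10, Tnc at 231 against 54.0 CPM and Postn, which encodes periostin, at 1.83 on the log2 scale. Mmp2 and Mmp14 stood at 2.07 and 1.38. In basal-like clusters alone Col4a1, Hspg2 and Mmp14 stood at -1.04, -0.32 and -0.13, and the matrix median was -0.43, the protease median -0.13 against 0.97, and the Wnt median -0.41 against 0.59. Those cells were low in YFP and lay mostly in cluster 12 in ear and cluster 5 in back. Igfbp7, Igfbp6 and Dcn stood at 3.88, 3.73 and 3.72. G2/M genes were higher in ear for 28 of 52 (median 1.03), and Krt5 and Krt14 were higher (1.05 and 0.87) while Krt15 was lower (-2.29).

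Back was at least 2-fold higher for 15 of 16 sebaceous genes (median -2.73), for Cst6, a cystatin of the upper follicle (66.7 against 2312 CPM), for Krt79 (-2.59) and for the follicle factor Gata6 (-2.75). Of 13 upper follicle genes 7 were lower in ear and 3 higher (median -1.17). B2m stood at 156 against 1588 CPM, log2 ratio -3.30. Krt2, Krt77 and Hoxa7 kept their wild-type direction: Krt2 stood at 6.22, Krt77 at -5.16 and Hoxa7 at -4.62. Of 6847 genes 383 were higher in ear and 470 lower. The higher count was 167 among SmoM2 cells with a YFP UMI and 159 in basal-like clusters, while the lower count stayed within 1.5 times its value.

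At 6 weeks ear and back differed in more genes, 558 higher and 676 lower in ear of 7078 (692 and 505 with median-of-ratios size factors). Stress keratinocyte genes led in ear, 14 of 15 higher with a median of 2.68: S100a9 stood at 660.2 against 4.22 CPM (156-fold, 95% interval 132 to 186), Sprr1b at 474 against 2.76 CPM (172-fold, 95% interval 139.9 to 214), Krt6a at 1851 against 109 CPM, log2 ratio 4.02 and the protease inhibitor gene Slpi at 4.85. In differentiated-like cells S100a9 stood at 2840 CPM in ear, mostly in clusters 7 and 15, and 6.33 CPM in back, mostly in clusters 1 and 23. Upper follicle genes were higher in ear for 5 of 13 measured members (median 0.82), and the retinoic acid enzyme gene Aldh1a3 stood at 3.75. Krt77 stood at 9.21 against 2546 CPM (276-fold lower, 95% interval 257 to 298), and Hoxa7, Pkib, Skint5 and Sema3d stood at -4.75, -4.12, -3.57 and -3.55.

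Hedgehog targets were close, with Gli1 at 57.3 against 48.9 CPM (log2 ratio 0.21), Ptch1 at 486 against 334 CPM (0.53) and Gli2 at -0.46, whereas Hhip and the transcription factor gene Prdm1 were higher in ear (1.71 and 2.20); the list median was 0.58 with 7 of 18 higher, and 0.22 among cells low in Krt1 and Krt10, 0.31 among cells with a YFP UMI and 0.32 with no minimum expression. Embryonic follicle genes had a median of 1.11 (11 of 20 higher, 1 lower), led by Lhx2 (2.24), the parathyroid hormone-like gene Pthlh (2.11) and Tbx1 (2.10). Wnt genes split: Wif1 stood at 3.27, and the Wnt target Axin2 and the ligand gene Wnt3 at -2.18 and -2.20. Matrix genes were higher for 9 and lower for 3 of 29, with Fbln1 at 2.21, Fras1 at 1.52 and Tnc at -1.53, and 10 of 21 protease genes were higher, with Ctsl at 2.37 and Mmp13 at 2.26. Krt14 was higher in ear (1.69); Dst and Dsp, which encode long plaque proteins, were lower (-1.58 and -1.29), in a comparison where the medians of 5 length bins ran from 0.50 for the shortest to -0.45 for the longest genes.

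Within ear SmoM2, 6 weeks was compared with 3 weeks to follow the SmoM2 cells over time. Barrier and stress genes were higher at 6 weeks, and so was the median of dissociation and immediate early genes, given under Other observations. Flg stood at 175 against 0.258 CPM (677-fold, 95% interval 447 to 1081), Klk7 at 204 against 2.06 CPM, log2 ratio 4.89, Sprr1a at 324 against 11.98 CPM, log2 ratio 4.27 and Sprr1b at 474 against 25.4 CPM, log2 ratio 3.98; 15 of 21 differentiation genes (median 1.32) and 13 of 15 wound genes (median 2.19) were higher. Upper follicle genes were higher for 10 of 13, with Cst6 at 908 against 66.7 CPM, log2 ratio 3.67 and Krt79 at 2.87. Follicle genes Ncam1, Pthlh and Lgr5 stood at 2.79, 1.80 and 1.51, and Wif1 at 2.15. Ptch1 and Gli1 were lower at 6 weeks (-0.68 and -0.42) and Hhip higher (1.56), and the Hedgehog median was -0.22.

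G2/M genes were lower at 6 weeks, 13 of 52 by at least 2-fold (median -0.73), with Mki67 at 153 against 379.7 CPM, log2 ratio -1.28 and Top2a at -1.22. Tnc stood at 66.5 against 231 CPM, log2 ratio -1.72, Igfbp3 at -2.39, Krt2 at -2.99, and the hemidesmosome genes Col17a1 and Dst at -1.14 and -1.17; Vcan, Fras1 and Mmp13 were higher (1.62, 1.52 and 2.35). Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 1.79. Of 6663 genes 318 were higher and 147 lower, and Nme2, Atp6v0c, Rnasek, Timm23 and Mrpl53 headed the higher ones and Ptp4a1, Chtf8 and Coro1b the lower ones here among genes that set both 3-week libraries apart.

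Within back SmoM2, differentiation genes were higher at 6 weeks and sebaceous genes lower, while of 17 Hedgehog genes 4 were higher and 1 lower (median 0.20, which turned to -0.34 among cells with a YFP UMI and -0.19 in basal-like clusters). Gli1 stood at 48.9 against 14.04 CPM (3.48-fold, 95% interval 3.11 to 3.91), Gli2 at 1.64, Ptch1 at 334 against 126 CPM (2.66-fold, 95% interval 2.56 to 2.77) and Krt17 at 6411 against 2038 CPM, log2 ratio 1.65. Differentiation genes were higher for 15 of 20 (median 1.73), with Flg2 at 45.5 against 0.147 CPM, Lor at 2.95, Krtdap at 4009 against 569 CPM, log2 ratio 2.81, and Dsg1a at 2.62. Krt6a and Krt16 stood at 2.61 and 2.70, Tnc and Vcan at 1.81 and 2.05, Wnt7b at 1.70 and Lgr5 at 1.53. Sebaceous genes were lower for 12 of 16 (median -1.85), with Scd1 at 489.9 against 2179.6 CPM, log2 ratio -2.14 and Mgst1 at -2.49, and within sebaceous gland-like cluster 19 the Scd1 level was 6582 CPM at 6 weeks and 8841 CPM at 3 weeks. Cst6 and Krt79 were lower (-1.46 and -0.95), and G2/M genes had a median of -0.59. Of 6868 genes 440 were higher and 302 lower, or 357 and 349 with median-of-ratios size factors, and the medians of 5 length bins ran from -0.26 for the shortest to 0.24 for the longest genes. Among cells with a YFP UMI, Ptch1, Gli1, Lor and Tnc stood at -0.24, -0.0307, -0.0852 and -0.0426 and Cst6 at 1.88, and in basal-like clusters Gli1, Wnt7b and Cst6 at -0.51, -0.13 and 0.47. With at least 1000 genes and at most 5% mitochondrial UMIs per cell, Scd1 stood at 0.0807. That filter leaves out most cells of cluster 19, whose median was 7.84% mitochondrial UMIs. YFP stood at 35.4 and 9.20 CPM in these libraries, and Nme2, Rnasek and Atp6v0c again headed the higher genes.

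**Figure D3:**
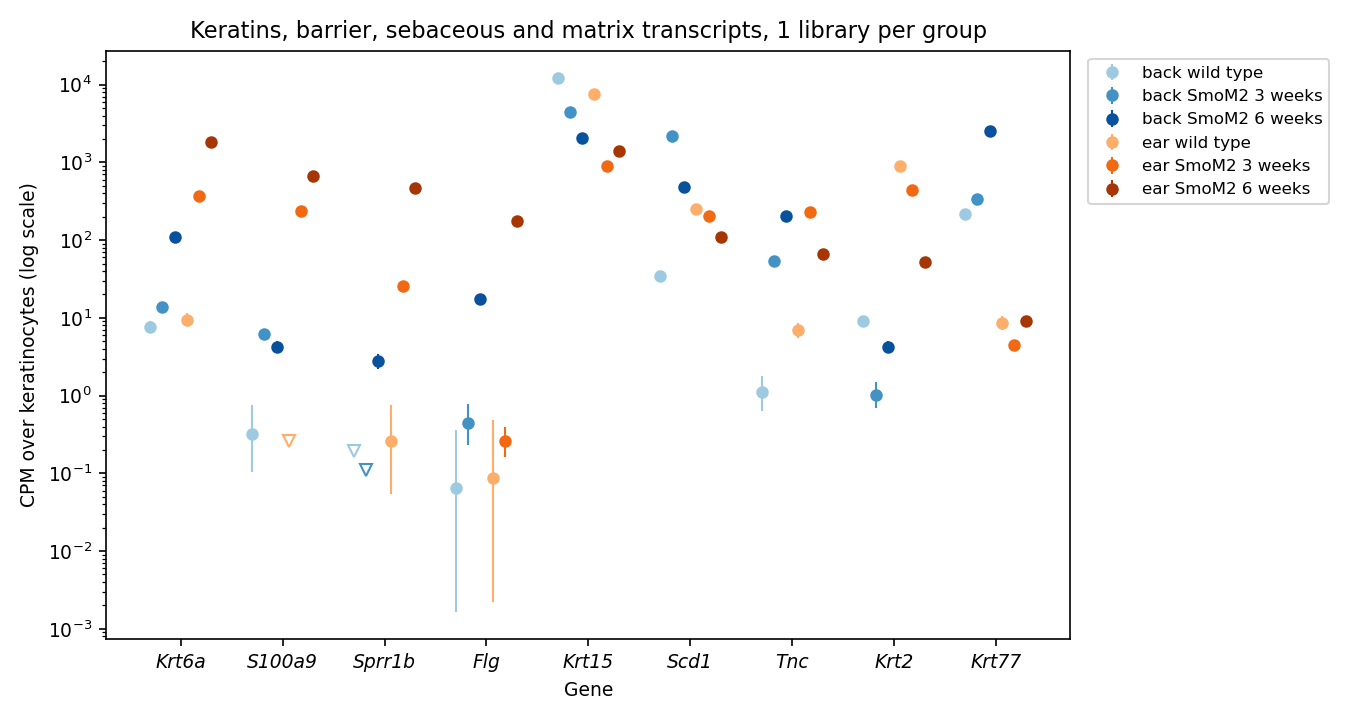
Level over keratinocytes (y axis, CPM, log scale) of 9 genes named in the text (x axis) in the 6 libraries, where points are libraries, bars are 95% Poisson intervals for counting error, and open triangles mark libraries with 0 counts at the floor of 3 counts. Krt6a lies at 7.64 and 9.53 CPM in the wild-type libraries and at 1851 CPM in ear SmoM2 at 6 weeks, and Scd1 at 34.4 CPM in back wild type and 2179.6 CPM in back SmoM2 at 3 weeks.

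The site difference in the response to SmoM2, the ear log2 ratio minus the back log2 ratio, had its highest list median for wound genes and its lowest for sebaceous genes at both times, out of 22 lists. At 3 weeks Krt6a differed by 4.13 (95% interval 3.85 to 4.39), Krt17 by 3.91, Igfbp7 by 3.76, Creb5 by 4.09 and Ptch1 by 2.20 (1.98 to 2.43), with a Hedgehog median of 0.89 and a sebaceous median of -4.76. That Hedgehog median was 0.12 with SmoM2 cells that held a YFP UMI and 0.49 with at least 1000 genes and at most 5% mitochondrial UMIs per cell. It was 0.56 with no minimum expression, 0.58 with each cell weighted equally and -0.00688 in basal-like clusters, which were low in YFP at both sites at 3 weeks. At 6 weeks Gli1 differed by -0.01 (-0.19 to 0.16) and Ptch1 by 0.14 (-0.07 to 0.36), intervals that hold 0, while Gli2 was lower (-0.91) and Hhip higher (1.44). Wound genes had a median difference of 2.17 at 3 weeks and 2.39 at 6 weeks, when 14 of 15 exceeded 2-fold, S100a8 by 4.42 and Sprr1a by 4.27. At 3 weeks 75.4% of back keratinocytes lay in clusters of low YFP. The Krt17 fold of ear over back at that time was 5.10 over all keratinocytes and 2.40 among cells with a YFP UMI. The 3-week differences of wound genes and Krt17 are thus not separated from how many cells carried the transgene. Upper follicle genes had a median difference of -0.90 at 3 weeks and 1.55 at 6 weeks. The sebaceous median was -3.11 at 6 weeks, from ear values below and back values above their wild types. With that filter on genes and mitochondrial UMIs the ear sebaceous medians against wild type turned from -0.75 and -0.91 at 3 and 6 weeks to 0.15 and 0.50. That filter leaves out most cells of sebaceous gland-like cluster 19, whose median was 7.84% mitochondrial UMIs, so it cannot decide the direction. Wild-type levels differed as well, and the response of each site is measured from its own wild type. In back at 3 weeks, sebaceous gland-like cluster 19 held YFP at 1.74 CPM and Ptch1 at 11.9 CPM. Upper hair follicle-like cluster 4 held 5.10 and 40.8 CPM, and Ptch1 stood at 12.7 CPM over keratinocytes of back wild type. At 6 weeks cluster 19 of back held YFP at 3.08 CPM and Ptch1 at 25.2 CPM. The sebaceous differences at both times and the upper follicle difference at 3 weeks are therefore not read as responses of cells with the transgene.

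Across genes, ear over back ratios at 3 weeks and 6 weeks, which share no library, had a Pearson r of 0.515 and a Spearman rho of 0.555 over 7610 genes, which are not independent replicates. Of these, 165 were at least 2-fold higher in ear at both times where independent lists would share 30.6, and 200 lower at both where 46.4 would be shared. The wild-type ratio correlated with them at 0.150 and 0.361 (rho 0.263 and 0.396).

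**Figure D4:**
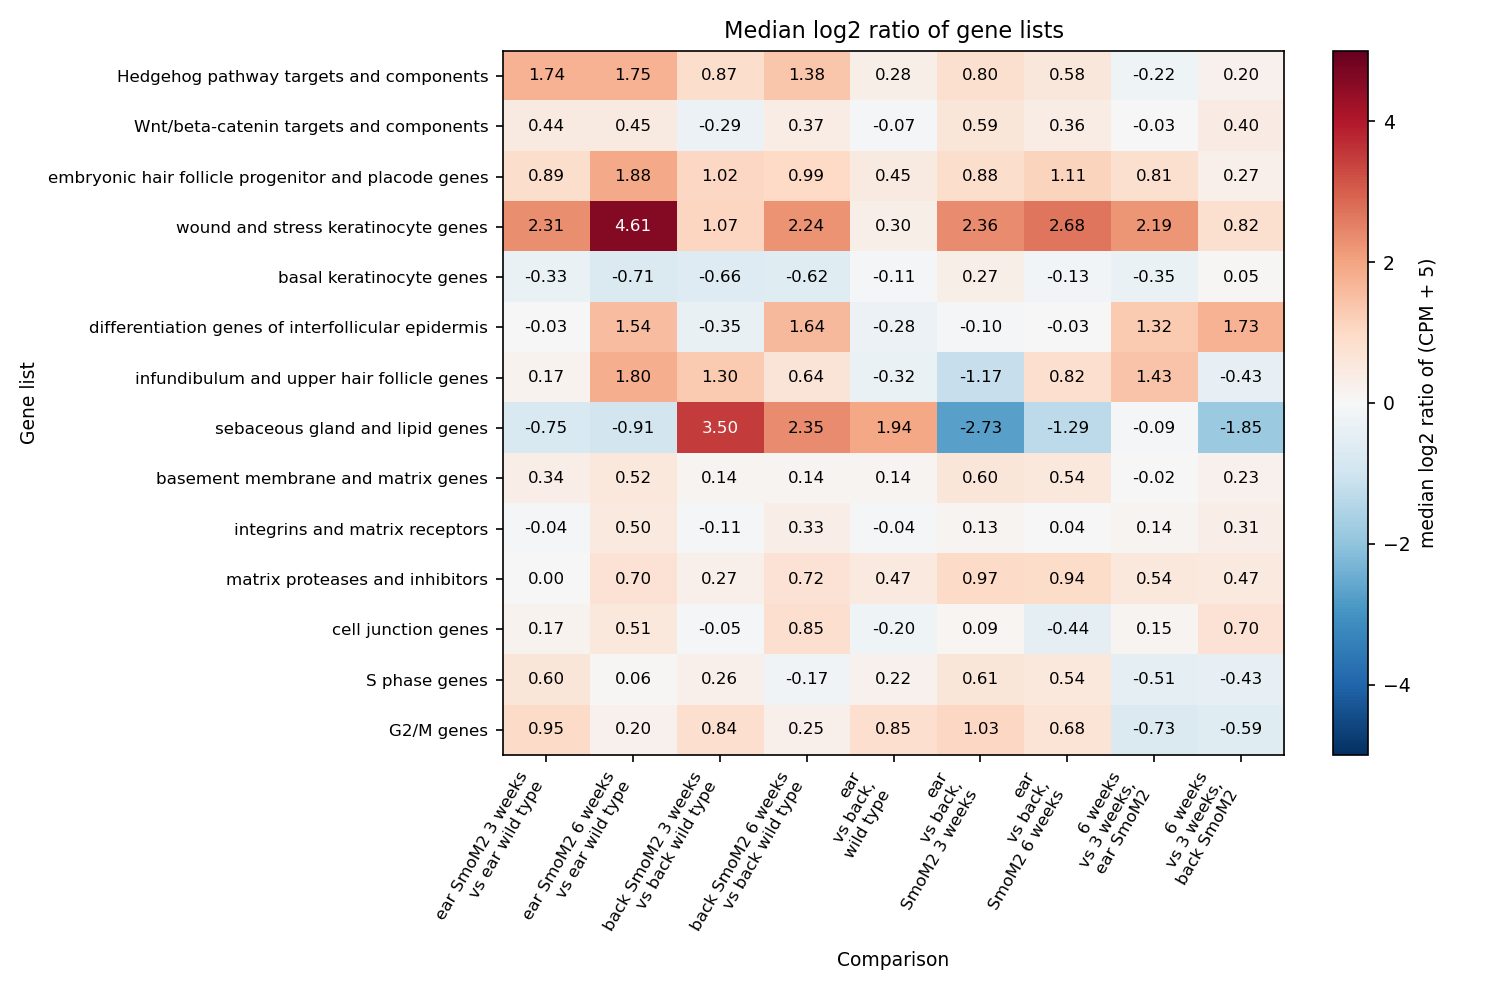
Median log2 ratio of (CPM + 5) for 14 gene lists (y axis) in the 9 comparisons (x axis), where each cell is coloured and printed with its median. Wound genes reach 4.61 in ear SmoM2 at 6 weeks against wild type, and sebaceous genes 3.50 in back SmoM2 at 3 weeks.

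Cells in cycle were counted as those with at least 3 UMIs of G2/M genes after thinning every cell to 1000 UMIs. The share was 21.4% in ear wild type (95% interval 19.2 to 23.8), 47.9% in ear SmoM2 at 3 weeks (46.5 to 49.4) and 41.6% at 6 weeks (40.4 to 42.7), and 19.5%, 30.0% and 28.3% in back. The G2/M genes made up 3441, 7041 and 4268 CPM in ear and 2341, 3723 and 2784 CPM in back. Without thinning the shares were 96.8%, 99.5% and 93.9% in ear and 97.2%, 96.6% and 81.6% in back. Differentiated-like cells, taken as background, reached 8.51%, 20.5% and 26.9% in ear and 14.4%, 24.5% and 26.0% in back, at median depths of 15798, 14842, 7927, 12323, 12294.5 and 4853.5 UMIs against 9671.5, 15716, 7331, 10894, 14999 and 4525 over all cells. In ear wild type this background came from 4 of 47 cells (95% interval 2.37 to 20.4), and in back wild type from 27 of 187 (9.74 to 20.3). Both intervals overlap those of the wild-type shares over all cells, 19.2 to 23.8 in ear and 17.5 to 21.7 in back. The background also differed between the groups. The wild-type shares at both sites and the SmoM2 shares in back, close to it, are therefore not read as cycling. The ear SmoM2 shares lay above this background but include it, so they are not read as the size of a cycling fraction. In ear at 6 weeks the share was 98.2% in 872 cycling-like cells and 33.5% in lower hair follicle-like cells. It was 59.6% in unnamed cells (317 of 532), a class with a median depth of 959 UMIs. Thinning left out 0, 43 and 668 ear cells and 0, 7 and 343 back cells, and free RNA remains open as a source of these UMIs.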

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

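The tests on YFP, on Ptch1 per cell with YFP, on depth, on shared exons and on the Cell Ranger version were chosen after the results they address had been seen; those on low-UMI clusters and on differentiated cells were written before theirs.

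Genes that SmoM2 libraries held at the opposite side of wild type in ear and in back stood out, a difference between groups that was not tested because each group had 1 library. Values are the ear log2 response minus the back log2 response. At 3 weeks Igfbp3, which encodes an insulin-like growth factor binding protein, had a difference of 3.75 (ear 1.249, back -2.497). The others were genes of lipid and sebaceous gland metabolism: at 3 weeks Mgst1 -7.50, Cers4 -7.46, Cidea -7.13, Gsta3 -6.68 and Lpl -6.11, and at 6 weeks Cers4 -5.58, Mgst1 -5.52, Elovl6 -5.52, Cidea -5.13, Fa2h -5.11, Scd1 -4.81, Gsta3 -4.66 and Soat1 -4.36. At 3 weeks 51 genes were at least 2-fold lower in ear and higher in back and 2 the reverse, of 7044; at 6 weeks the counts were 35 and 2, of 7258. Within sebaceous gland-like cluster 19 the Scd1 level was 8841 CPM in back and 7558 CPM in ear at 3 weeks. In these libraries the cluster held YFP at 1.74 and 12.4 CPM, and Ptch1 at 11.9 and 48.0 CPM. At 6 weeks cluster 19 held YFP at 3.08 CPM in back and 9.27 CPM in ear, beside 35.4 and 39.9 CPM over keratinocytes. The sebaceous differences are not read as responses of cells with the transgene. With at least 1000 genes and at most 5% mitochondrial UMIs per cell, the sebaceous medians of ear against wild type turned from -0.75 to 0.15 at 3 weeks and from -0.91 to 0.50 at 6 weeks. Cluster 19 had a median of 7.84% mitochondrial UMIs, and unnamed cluster 18, with the sebaceous markers Mgst1 and Pparg, one of 6.71%. This filter thus leaves out most cells of both clusters and cannot decide the direction in ear.

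Data outside the comparisons held a second cell tag in each wild-type library. CMO303, the main tag of ear wild type with 87.4% of its tag UMIs, made up 6.603% of tag UMIs in back wild type. CMO304, the main tag of back wild type with 93.4%, made up 12.6% in ear wild type. No barcode of either library held most of its tag UMIs from the second tag, and no source was tested.

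Hedgehog target transcripts were lower in the back than in the ear library 3 weeks after induction, with Ptch1 6.22-fold apart. A lower depth of the back library was argued against, since the median UMI count per keratinocyte differed by a factor of 1.05. Fewer cells with the YFP transcript in the back library are a candidate explanation: YFP was 4.02-fold higher in ear, and clusters of low YFP held 75.4% of back keratinocytes. Against this stands the sort, which per the labels was gated on YFP and should have kept out cells without the transgene; how such cells would have passed it was not tested. A lower level of Hedgehog targets per cell with YFP cannot be told apart from this. The Ptch1 ratio of 2.10 among cells with a YFP UMI lay between what both predict, and the Hhip ratio among these cells was 0.528, higher in back. YFP UMIs were also seen in cells named as other types, where free RNA and doublets with keratinocytes were not told apart as their source. Body site itself stays open as an untested biological explanation.

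Genes at least 2-fold lower in both 3-week libraries than in each of the 4 others may be low because the 3-week feature lists hold gene models that share their exons, where a read that falls in both would count for neither. Of 52 such genes 65.4% overlapped such a model, against 2.17% of all expressed genes. The other members of the set had no such overlap and stay unexplained.

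Long transcripts were higher in the back 6-week library, with a rank correlation of exonic length and ratio of 0.45 against wild type. The Cell Ranger version was argued against, as ear at 6 weeks, made with the same version, gave -0.0901. More differentiated cells were argued against as the whole source, as the correlation was 0.439 among cells with Krt1 and Krt10 under 0.5% of UMIs. Clusters of cells with few UMIs cannot be told apart from other sources by leaving them out: the correlation was then 0.452, but these clusters held 3.01% of the keratinocyte UMIs of the library, and no named gene ratio moved. With each cell weighted equally, which gives cells with few UMIs more weight, it was 0.515. The nuclear transcript Malat1 stood at 28532 CPM in this library and 16583 CPM in back wild type. A difference in the preparation of this library and a difference of back skin at this time both stay open as untested.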

How the results depend on the processing

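Only the settings with YFP-positive cells, with genes of like length, without low-UMI clusters, without overlapping genes and with cycling among keratinocytes were chosen after the data were seen. Gene values below are log2 ratios. The labels name no animals that groups share, and site was not fitted with the 3 conditions as blocks. Of 2508 list medians under an alternative, 1347 stayed within counting error, 1148 moved and 13 reversed; 153 of those that moved crossed 0 from a reported size of at most 0.48. Of 210 counts of genes, 185 stayed within 1.5 times the count reported. Of 2832 values of genes named in the text, 1581 stayed, 1229 moved, 3 of them across 0, and 22 reversed. Of 260 class shares, 151 stayed and 109 moved. Causes were not tested except where the alternative itself sets them.

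With basal-like clusters only, a much smaller set of cells, ear at 3 weeks had 54 genes higher and 76 lower than wild type, back at 3 weeks 200 and 55, and back at 6 weeks 120 and 21. Ear against back had 102 higher in wild type and 159 at 3 weeks, and back over time 99 and 66. Hedgehog medians were 0.14 in ear and 0.39 in back at 3 weeks, 0.21 in back at 6 weeks and 0.0900 between sites at 3 weeks. The site difference in response at 3 weeks was -0.00688, a sign change of very small size. At 3 weeks these clusters held YFP at 6.77 CPM in ear and 7.60 CPM in back, so their Hedgehog ratios say little on cells with the transgene. Of 391 ear cells 388 lay in cluster 12, and all 127 back cells in cluster 5, so different clusters were compared. Basal markers named both clusters, which favours a higher basal list by construction. List medians reversed for sebaceous genes in ear at 3 weeks (0.0920), basal genes in back (0.42 and 0.32), and between sites at 3 weeks for Wnt (-0.41), matrix (-0.43), protease (-0.13), S phase (-0.34) and mesenchymal genes (-0.17). Genes that reversed were Smo (-0.18) and Wnt7b (-0.0876) in ear at 3 weeks, Krt14 (0.14), Krt5 (0.24), Smoc2 (0.14) and Sparc (0.45) in back at 3 weeks, and Fcgbp (0.23), Il1r2 (0.0131), Dll1 (0.48) and Tgfb2 (-0.11) at 6 weeks. Between sites at 3 weeks they were Col4a1 (-1.04), Hspg2 (-0.32) and Mmp14 (-0.13), and in back over time Cst6 (0.47), Gli1 (-0.51) and Wnt7b (-0.13). The setting was not run for ear at 6 weeks, which held 8 basal-like cells.

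With all cell types, 419 and 423 genes were lower in ear at 3 and 6 weeks, and 442 were higher in ear than back wild type, where T cell-like cells enter by construction. Hedgehog medians were 1.46 and 1.51 in ear, 1.27 in back at 6 weeks and 0.61 between sites at 6 weeks, and the 6-week response difference 0.0557.

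With 1 CPM added in place of 5, Hedgehog medians were 1.97 and 2.59 in ear, 1.47 in back at 6 weeks and 1.04 between sites at 3 weeks, and the 6-week response difference 0.21. With no minimum expression they were 1.06, 1.21, 0.81, 0.70, 0.73 and 0.32 for ear at 3 and 6 weeks, back at 3 and 6 weeks and the sites at 3 and 6 weeks, and the response differences 0.56 and -0.00732; mesenchymal genes reversed to 0.0752, 0.0245 and 0.0185 in ear at 6 weeks and back at 3 and 6 weeks, as members near 0 enter by construction.

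With each cell weighted equally, Hedgehog medians were 1.54 and 1.85 in ear, 0.99 and 1.05 in back and 0.78 between sites at 6 weeks, the 3-week response difference was 0.58, and back at 6 weeks had 1011 genes higher and 199 lower. With median-of-ratios size factors, back had 318 genes lower at 3 weeks and 321 higher and 372 lower at 6 weeks, and ear wild type 138 lower than back. Hedgehog medians were 1.67 in ear at 6 weeks, 0.57 and 1.00 in back and 0.69 between sites at 6 weeks, with response differences of 1.011 and 0.65.

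With ratios centred on genes of like length, back at 6 weeks had 368 genes higher. Hedgehog medians were 1.53 and 1.49 in ear, 0.74 and 1.08 in back and 0.43 between sites at 6 weeks, and the 6-week response difference 0.71.

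With at least 1000 genes and at most 5% mitochondrial UMIs per cell, sebaceous genes in ear reversed to 0.15 and 0.50, and Scd1 in back over time to 0.0807. This filter leaves out most cells of sebaceous gland-like cluster 19 by construction, as their median was 7.84% mitochondrial UMIs. Back had 99 genes lower at 3 weeks, and 259 higher and 187 lower over time. Hedgehog medians were 1.19 and 1.17 in back and 0.72 and 0.48 between sites, and the 3-week response difference 0.49. Shares in cycle were 26.3%, 51.3% and 37.5% in back at 6 weeks and ear at 3 and 6 weeks.

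With only SmoM2 cells that held a YFP UMI, 167 genes were higher in ear than back at 3 weeks and 250 higher in back over time. Hedgehog medians were 1.66 in ear at 6 weeks, 1.60 in back at 3 weeks, and 0.42 and 0.31 between sites, with response differences of 0.12 and 0.28. In back over time Cst6 (1.88), Gli1 (-0.0307), Lor (-0.0852), Ptch1 (-0.24) and Tnc (-0.0426) reversed. With cells low in Krt1 and Krt10, Hedgehog medians were 0.82 and 1.52 in back and 0.22 between sites at 6 weeks, and the 6-week response difference 0.22.

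Shares in cycle, in the order back wild type, 3 and 6 weeks and ear wild type, 3 and 6 weeks, were 97.2%, 96.6%, 81.6%, 96.8%, 99.5% and 93.9% without thinning, where depth sets them, and 5.75%, 13.0%, 9.10%, 9.47%, 31.4% and 19.7% with at least 5 G2/M UMIs. Among keratinocytes the ear wild-type share was 24.3%. Without low-UMI clusters, without overlapping genes or with doublets kept, no count of genes, Hedgehog median or site difference in response moved, nor did a share in cycle with doublets kept. Other values did: 1, 15 and 7 of 198 list medians moved in these settings, and with doublets kept 5 gene values and 18 of 65 class shares. Depth limits genes with few UMIs in the shallower wild-type libraries. Fold intervals span more than 10-fold for genes such as Flg, Gli1 in back, Mmp13, Pi15, Sprr1b, Fa2h, Ncam1, Vcan and Hoxb7.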

Other observations

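All observations here describe values seen in the data, and no test of an explanation was made. The list of BMP and TGF-beta genes had medians of 0.50, 0.38, 0.44 and 0.62 for ear at 3 and 6 weeks and back at 3 and 6 weeks against wild type, where 5 of 21, 8 of 19, 4 of 20 and 5 of 20 members were at least 2-fold higher and 0, 2, 2 and 1 lower. Fst, which encodes the activin antagonist follistatin, stood at 1.87, 2.96, 1.67 and 1.30, Tgfb2 at 2.35 and 2.63 in ear and 1.42 in back at 6 weeks, and Inhba, which encodes an activin subunit, at 2.76 in back at 6 weeks. Of 10 Notch genes 5 were higher and 1 lower in back at 6 weeks (median 0.98), with Notch2 at 1.90 and the ligand gene Dll1 at -1.24. In basal-like clusters of back at 6 weeks Tgfb2 and Dll1 stood at -0.11 and 0.48. Between the sites at 6 weeks the Notch median was -0.75, with Notch3 at -2.23.

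Interferon and antigen genes had list medians of -0.53 in wild type, -1.27 at 3 weeks and -0.69 at 6 weeks for ear over back, with 8 of 17, 11 of 17 and 6 of 18 lower in ear, and B2m, which encodes the light chain of class I molecules, at -1.66, -3.30 and -1.46. Ifitm3 went the other way at 6 weeks (2.44). Mesenchymal transition genes had medians of -0.39, -0.62, -0.79 and -0.90 with SmoM2, in the same order of comparisons as above, from 6 measured members each. With no minimum expression the last 3 turned to 0.0752, 0.0245 and 0.0185. YAP and TAZ targets lay at -0.33, -0.33, -0.17 and 0.13, the last of which turned to -0.17 with size factors, and Ccn2 stood at 2.51 and 2.59 in back. Targets of p53 had medians of 0.35, 0.48, 0.11 and 0.23, the back values turning to -0.20 and -0.10 with size factors, and Cdkn1a stood at 1.52 and 1.40 at 6 weeks. Dissociation and immediate early genes had medians of 0.64 and 0.84 for 6 over 3 weeks in ear and back, the latter 0.19 in basal-like clusters, with Fos at 2.87 in back. Against wild type their medians at 6 weeks were 0.72 in ear and, in back, 0.41, or 0.0245 with size factors. Energy metabolism genes were higher in ear than back at 6 weeks (median 1.02, 10 of 19), with Gapdh at 1.67, in a comparison where short transcripts had higher ratios than long ones; centred on genes of like length the values were 0.65 and 1.62.

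Dcn, which encodes the matrix proteoglycan decorin and was looked at in classes after its values were seen, stood at 645 CPM in the unnamed clusters of ear at 3 weeks, 539 CPM at 6 weeks in ear and 367 CPM in back at 6 weeks. These cells lay mostly in clusters 2 and 17, 8 and 2, and 13 and 14 of the respective libraries, so different clusters are set side by side, of which 8 and 13 were low in UMIs. Col1a1 in the same clusters stood at 0, 1.70 and 0.212 CPM. Lower hair follicle-like cells, in clusters 0, 9 and 26, held Lgr5 at 170 CPM in ear wild type, 336 and 249 CPM in ear at 3 and 6 weeks, and 265 and 317 CPM in back at 3 and 6 weeks, while Ptch1 stood at 115, 1042, 948, 921 and 1294 CPM in the same libraries. Different clusters held most of these cells: cluster 26 held 35 of 47 in ear wild type, 25 of 37 in back at 3 weeks and 82 of 125 in back at 6 weeks, and cluster 0 held 145 of 190 in ear at 3 weeks and 2033 of 2936 in ear at 6 weeks.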
